A study of Homo sapiens with 39 samples.

How the data were processed

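The series holds RNA-seq libraries of human breast cancer cell lines in 3 states, which were cultured cells (10 libraries), mouse intraductal (MIND) tumours (19) and fat pad (FP) tumours (10). Per the labels' protocols, RNA was purified on RNeasy columns and made into polyA-selected, stranded Illumina TruSeq libraries. The submitters' processing notes name TopHat, DESeq2 and the hg38 genome, without a version and without saying what each was used for. Each of 4 deposited tables held a raw read count per Ensembl gene and library for 58676 gene IDs, with the gene's symbol, biotype and coordinates beside it. The counting program, the annotation release and the strand counted were not given in the sources used here. Per the file headers, the columns of both MIND tables carry a tag for filtered reads, the nature of which is not stated, and the columns of the culture and FP tables carry no such tag. Every value was a whole number and the column totals differed, as raw counts do. The tables were joined by gene ID, and at most 27 symbols changed between tables. Symbols shared by several IDs numbered 1524, and each ID was kept as its own gene. Tables held 0 summary lines. A total of 1 per-sample column, which the labels tie to no sample of its table, was not used here.

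Groups followed the labels. Cell lines named in the sample titles tied the libraries of the 3 states, and the lines were numbered 1 to 10 for the alternatives that leave out 1 line. Main comparisons used the 30 libraries of the 10 lines with all 3 states, and the 9 further MIND tumours entered the SMAD4 panel and the closing section. A check of the pairing correlated, over pairs of libraries of the same line, the departures from the state means. For the 27 pairs of the other 9 lines the lowest value was 0.338 (T-47D culture and FP tumour) and the median 0.753. For the libraries labelled SK-BR-7 the values ran from -0.0871 to 0.0658. The block was kept, as fixed beforehand.

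Comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. Genes were filtered with filterByExpr by group, which left 16003, and scaled with TMM in edgeR 4.0.16 (R 4.3.3). Differential expression was tested with the edgeR quasi-likelihood F-test, with cell line as a block and the 3 states in 1 fit, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 differences are from that fit, with standard errors from the fitted dispersion and n as the number of lines. CPM levels used the TMM-scaled totals, and log2 CPM a prior count of 2. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 27 lists with enough tested members, and again with the correlation estimated. The 29 lists were hypoxia and glycolysis, cell cycle, cholesterol synthesis, type I interferon response, antigen presentation, oestrogen receptor targets, luminal identity, basal identity, epithelial junction and identity, epithelial-mesenchymal transition, TGF-beta and SMAD targets, TGF-beta and BMP pathway components, extracellular proteases, unfolded protein response, amino acid starvation response, p53 targets, glucocorticoid response, immediate early genes, replication-dependent histones, ribosomal proteins, the mitochondrial genome, milk proteins, and markers of fibroblasts, endothelium, leukocytes, adipocytes, smooth muscle and pericytes, skeletal muscle and erythroid cells. The skeletal muscle list (2 tested members) and the erythroid list (0) were given as levels only.

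Genes were named by rule. For each comparison these were the 10 largest increases and the 10 largest decreases among genes with an adjusted p below 0.05, an absolute log2 difference of at least 1, a mean log2 CPM of at least 1, a symbol, and the same direction in at least 9 of 10 lines. Up to 4 members with the smallest adjusted p, in the direction of the list, were named for each list called by camera. SMAD4, the levels of ESR1, ERBB2, CDH1 and VIM per line, and the highest member of each list of other cell types were always named. For the own-line comparison, each tumour was correlated with the 10 cultures over all tested genes (Spearman), and the number closest to their own line was compared with chance by an exact binomial test. The relations of SMAD4 to 6 list scores used Pearson and Spearman correlations over 19 tumours with 100000 permutations, or all permutations with 9 tumours. A list score was the mean of standardised log2 CPM over the list's expressed members. The GC content of each gene was taken from its longest transcript in the GENCODE reference for hg38, which gave a value for 100% of tested genes.

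Alternatives fixed beforehand were RLE and upper-quartile scaling in edgeR, the DESeq2 1.42.0 Wald test, no filter beyond a nonzero total, a filter at a mean of 5 CPM, protein-coding genes alone, a minimum absolute log2 difference of 1, no block, a fit of the 2 states compared, each line left out in turn, fry in place of camera, a prior count of 0.5, the SMAD4 relations within each table or without the 2 tumours farthest from the median, Pearson correlation over the 1000 most variable genes, and MIND and FP differences from separate sets of 5 lines. Added after the data were seen were a fit without the SK-BR-7 libraries, offsets corrected for GC content, leaving out lines in the list tests, and 3 variants of the SMAD4 relations. Total counts per library ran from 6663586 to 26341390, so that 3 counts, the upper limit that a count of 0 allows, stood for 0.114 to 0.450 CPM. Intervals on single levels are exact Poisson 95% intervals.

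The scripts were tested on simulated counts drawn from the real means and totals with known changes. In the MIND to culture simulation, 5.97%, 32.8% and 74.2% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, and 5% of calls were false. In the FP to culture simulation these shares were 5.97%, 23.9% and 59.1%, with 3.28% false, and in the FP to MIND simulation 6.72%, 40.3% and 68.2%, with 3.14% false. A cell cycle list lowered 1.5-fold in simulated counts had a camera adjusted p of 2.47e-15, and 0 other lists of 27 were called. Simulated genes were drawn independently, whereas the estimated correlation of the real cell cycle list was 0.644 for MIND against culture. The simulation therefore cannot show how often camera calls a list falsely in these data.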

Results

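RNA-seq read counts per gene were available for 39 libraries of human breast cancer cell lines. Libraries from cultured cells covered 10 lines. Mouse intraductal (MIND) tumours, grown from cells injected into the mammary ducts, gave 19 libraries, and tumours grown in the mammary fat pad (FP) gave 10. The 10 lines with all 3 states were Evsa-T, MCF-7, MCF10DCIS.com, MDA-MB-231, SK-BR-5, SK-BR-7, SUM52PE, SUM149PT, SUM159PT and T-47D. The other 9 MIND tumours came from BT-20, BT-474, CAMA-1, HCC1937, MDA-MB-175-VII, MDA-MB-453, MDA-MB-468, SK-BR-3 and SUM225CWN. Total counts ranged from 17658122 to 26341390 for cultures, from 6759454 (SK-BR-3) to 23141142 (SUM149PT) for MIND tumours, and from 6663586 (MCF-7) to 17918233 for FP tumours. Mitochondrial genes held 8.86% ± 6.28 (SD, n = 10) of the counts in cultures, 10.6% ± 5.88 (n = 19) in MIND tumours and 9.13% ± 4.99 (n = 10) in FP tumours. Each line gave 1 library per state, so that no replicate of the same line existed and edgeR p-values below measure the spread between lines. Camera p-values at the preset correlation compare the genes of a list with the other tested genes, and are no measure of the spread between lines. Cultures, MIND tumours and FP tumours stood in different deposited tables, so that state and table could not be separated. Per gene, a median of 66.0% of the variance lay between lines and 6.86% between states.

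The first comparison asked whether each tumour retained the expression pattern of the line it was labelled with. Of 20 tumours with a cultured counterpart, 18 had their highest Spearman correlation with the culture of their own line (exact binomial p = 1.56e-16, chance 10%). The test took the MIND and the FP tumour of a line as independent, which they are not, so this p-value overstates the evidence. Own-line correlations of these 18 tumours ran from 0.868 to 0.959, and their highest correlation with another line was 0.875. The MIND tumour labelled SK-BR-7 correlated at 0.742 with the SK-BR-7 culture and at 0.839 with Evsa-T. The FP tumour labelled SK-BR-7 correlated at 0.731 with that culture and at 0.917 with MCF-7. Over all 39 libraries, the nearest library to the MIND tumour labelled SK-BR-7 was the SUM225CWN MIND tumour (0.924). The nearest to the FP tumour labelled SK-BR-7 was the MCF-7 FP tumour (0.992). The 9 MIND tumours of lines without a culture could not be checked against their own line. Among them, the SK-BR-3 MIND tumour was nearest to the FP tumour labelled SK-BR-7 (0.913). Both tumours of the same line correlated with each other at a median of 0.952 over the other 9 lines (0.912 to 0.982), and at 0.785 for the libraries labelled SK-BR-7. Unless stated otherwise, the comparisons below still count the libraries labelled SK-BR-7 as 1 matched line of the 10. ERBB2, the HER2 receptor gene, measured 107 CPM in the SK-BR-7 culture, 21042 CPM in the MIND tumour and 208 CPM in the FP tumour with that label. ESR1, the oestrogen receptor gene, measured 0 CPM in the SK-BR-7 culture (0 counts, which allows up to 0.129 CPM), 1.11 CPM in the MIND tumour and 361 CPM in the FP tumour. All intervals and floors in this text cover counting error only.

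**Figure D1:**
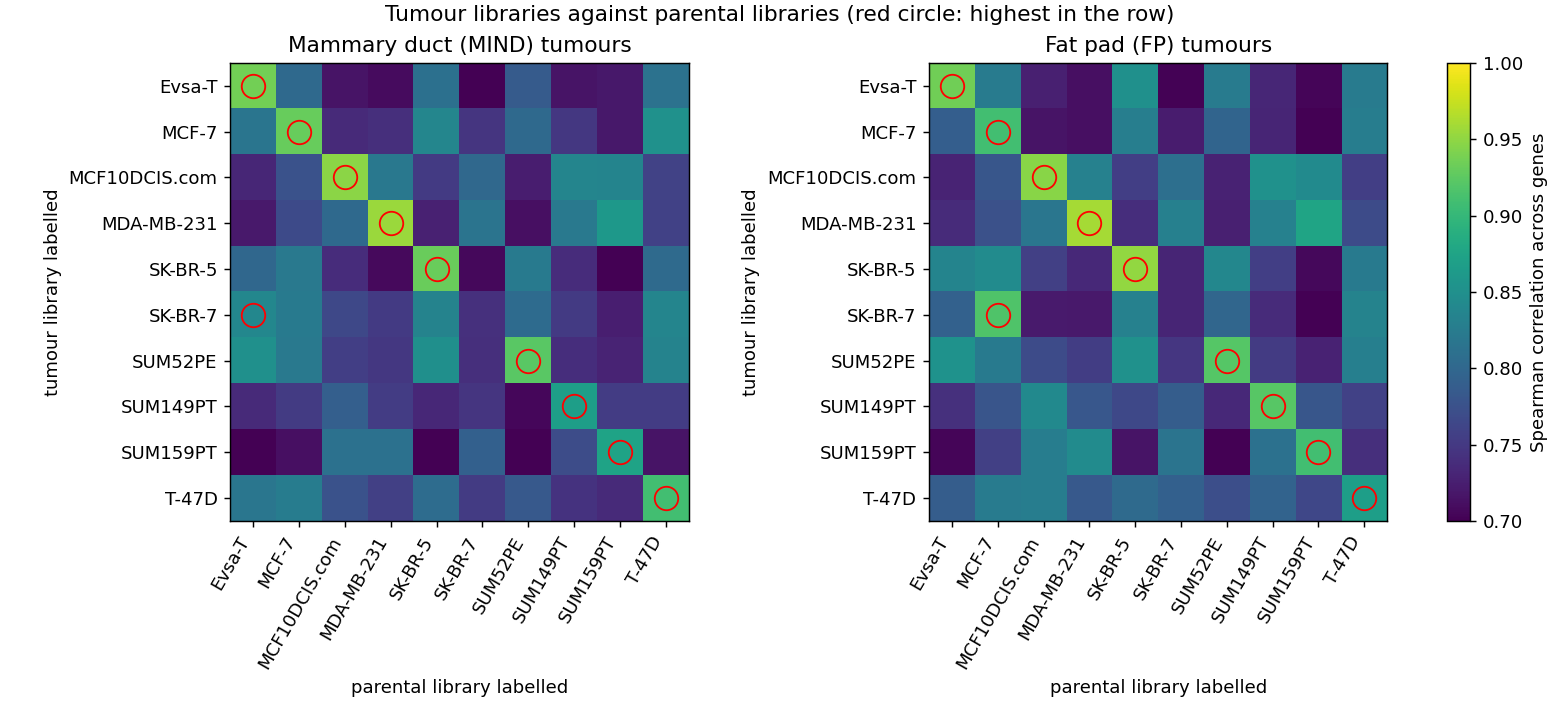
Spearman correlation of each tumour library with each cultured library across the 16003 tested genes, for MIND and FP tumours. A red circle marks the highest value for each tumour.

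The series design text asks what drives the invasiveness of breast cancer, and MIND tumours place the cells inside the ducts. Comparing MIND tumours with cultures of the same 10 lines asked which genes differed between ductal growth and culture. Of 16003 tested genes, edgeR called 2969 at an adjusted p below 0.05, 1437 higher and 1532 lower in MIND tumours. Calls with at least a 2-fold difference numbered 865 higher and 605 lower. The share of higher calls was 48.4%, against 63.0% with upper-quartile scaling. KRT14, a keratin of basal and myoepithelial cells (ENSG00000186847, hg38 chromosome 17, 41582279 to 41586921), had the largest increase and rose by 7.82 ± 1.04 on the log2 scale (SE, n = 10 lines, edgeR adjusted p = 0.000135), from a mean of 2.60 to 365 CPM, in 10 of 10 lines. KRT5 rose by 4.53 ± 1.23 in 10 of 10 lines, from 107 to 795 CPM. KRT17 rose by 4.60 ± 1.21, from 123 to 459 CPM, and KRT6A by 2.97 ± 0.87 in 8 of 10 lines. Single tumours carried these means, with 71.4% of the summed KRT14 level of MIND tumours in SUM149PT (median 2.12 CPM) and 50.2% of that of KRT17 in SUM159PT (median 78.0 CPM). In the basal identity list, 5 of 14 measured members rose and 0 fell, with the same 5 when adjusted over the list alone (camera adjusted p = 0.0157; adjusted p = 0.659 with an estimated correlation). The mean list difference was positive in 10 of 10 lines, from 0.06 in MCF-7 to 5.21 in SUM159PT. The SUM159PT MIND tumour also had the largest list means over lines for fibroblast markers (5.06) and for smooth muscle and pericyte markers (2.93). Gains of KRT5 plus KRT14 above 100 CPM were found in the tumours of MCF10DCIS.com, SUM149PT, SUM159PT and T-47D and in no other of the 10 lines.

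Interferon-induced genes were higher in MIND tumours than in culture. In the type I interferon response list, 14 of 24 measured members rose and 0 fell, and 17 rose when adjusted over the list alone (camera adjusted p = 1.09e-08; adjusted p = 0.485 with an estimated correlation). XAF1 rose by 4.74 ± 0.73 (edgeR adjusted p = 0.000411), from a mean of 2.72 to 70.6 CPM (53.6% of the latter in SUM159PT), in 10 of 10 lines. OAS2, which makes the activator of RNase L, rose by 3.93 ± 0.70 in 10 of 10 lines, from 8.57 to 117 CPM. OAS1 rose by 2.41 ± 0.51 in 10 of 10 lines, and IFIT1 by 2.14 ± 0.45 in 9 of 10, from 11.4 to 74.0 CPM. The list mean was higher in 10 of 10 lines, at 1.83 ± 1.45 (SD), with the smallest difference in Evsa-T (0.16) and the largest in the tumour labelled SK-BR-7 (4.20).

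Cell cycle genes, immediate early genes and genes of the amino acid starvation response were lower in MIND tumours than in culture. In the cell cycle list, 13 of 25 members fell and 0 rose, and 17 fell when adjusted over the list alone (camera adjusted p = 6.49e-08; adjusted p = 0.659 with an estimated correlation). The mitotic kinase gene PLK1 fell by 1.37 ± 0.25 (edgeR adjusted p = 0.00129), from 123 to 45.2 CPM. AURKA fell by 1.16 ± 0.23, the replication licensing gene MCM2 by 1.12 ± 0.24 and CDC20 by 1.01 ± 0.25. The cell cycle list mean was lower in 7 of 10 lines. Of 16 immediate early genes, 9 fell and 1 rose in all tested genes and over the list alone (camera adjusted p = 0.000108; adjusted p = 0.256 with an estimated correlation). FOS fell by 3.81 ± 0.57 (edgeR adjusted p = 0.000317), from 272 to 27.0 CPM, JUNB by 2.44 ± 0.36 and IER3 by 2.31 ± 0.37, each in 10 of 10 lines. IER2 fell by 1.23 ± 0.22 in 9 of 10 lines. Of 16 genes of the amino acid starvation response, 9 fell and 0 rose, also over the list alone (camera adjusted p = 0.000154; adjusted p = 0.256 with an estimated correlation). The 1-carbon enzyme genes MTHFD2 and SHMT2 fell by 0.93 ± 0.16 and 0.83 ± 0.15 in 10 of 10 lines, MTHFD2 from 334 to 172 CPM. SLC3A2 fell by 1.11 ± 0.26 in 10 of 10 lines, and CHAC1 by 2.17 ± 0.51, from 16.4 to 3.85 CPM.

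**Figure D2:**
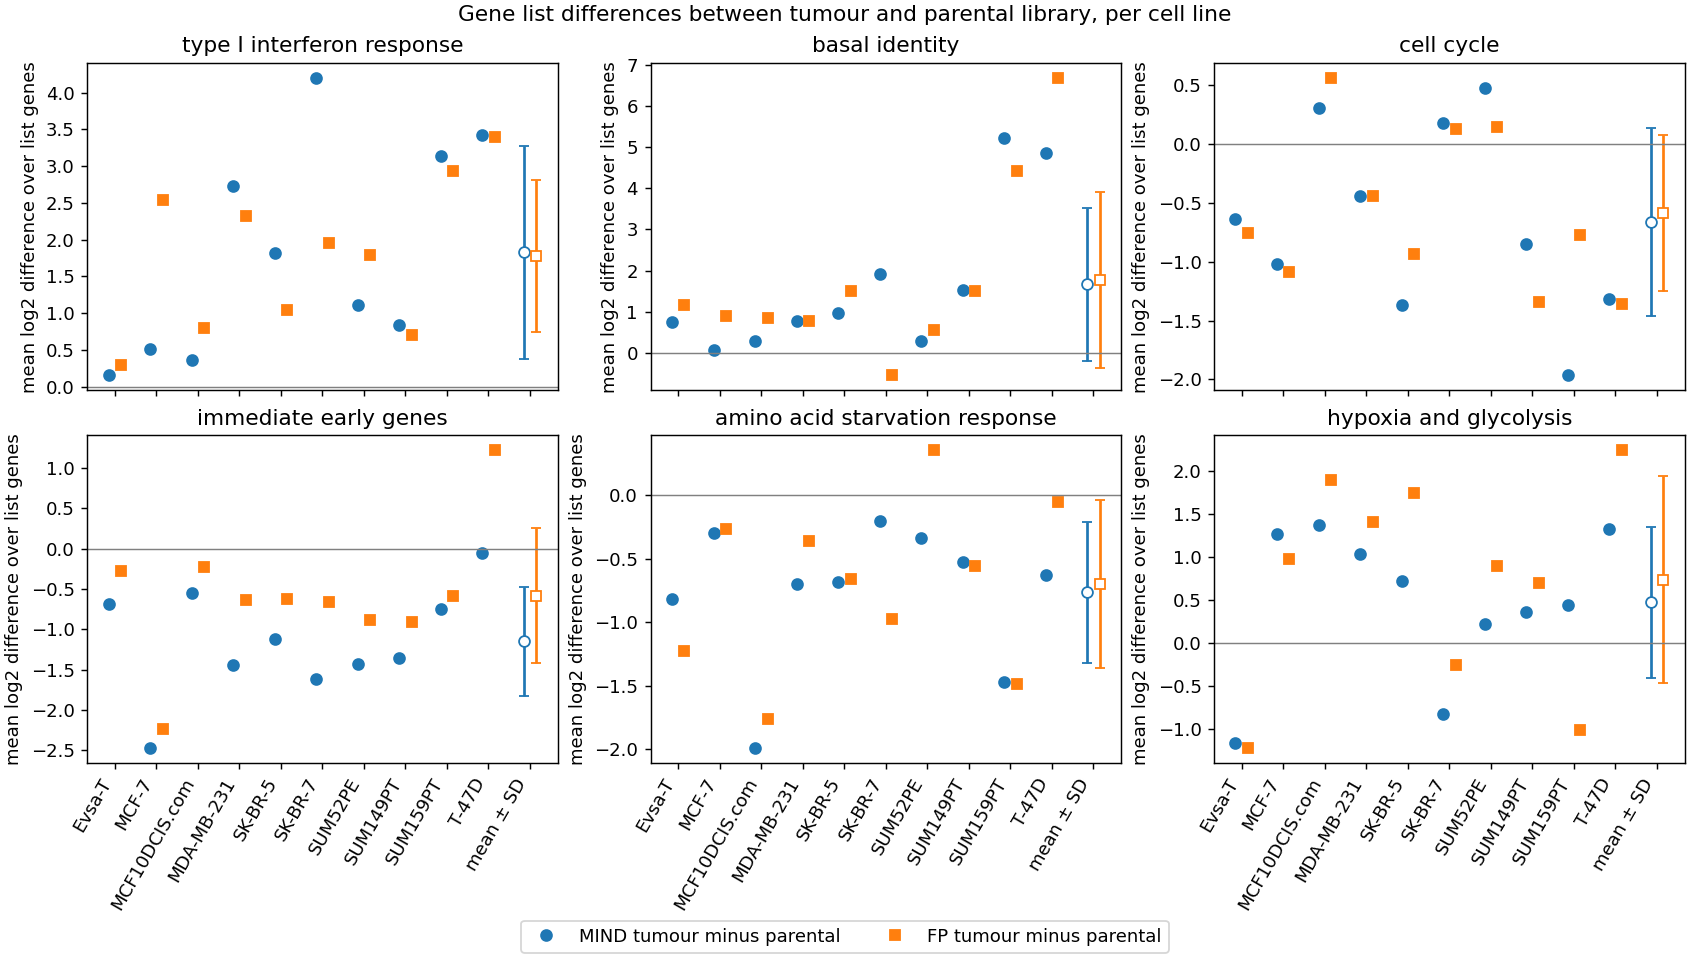
Mean log2 difference from culture over the members of 6 gene lists, per line, in MIND and FP tumours. Bars give the mean and SD over 10 lines.

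COL1A2, a chain of type I collagen, rose by 5.74 ± 1.30 (edgeR adjusted p = 0.00458) in 9 of 10 lines, from 0.174 to a mean of 1167 CPM. Its level was 11472 CPM in the SUM159PT MIND tumour and 27.6 CPM or less in the other 9. Whether these reads came from the cancer cells or from mouse cells in the tumours was not tested. FMOD rose by 5.63 ± 1.49, SOSTDC1 by 5.45 ± 1.52, NELL2 by 5.29 ± 1.66 and GABRP by 5.20 ± 1.52. FAM3D rose by 5.71 ± 1.08, LMO3 by 4.86 ± 1.12, and the receptor gene TNFRSF19 by 4.76 ± 0.85 in 10 of 10 lines, from 0.903 to 26.8 CPM. AP002982.1 (ENSG00000213750, chromosome 8, 97624203 to 97625079), annotated as a processed pseudogene, rose by 7.51 ± 0.60 in 10 of 10 lines, from 0.0233 to 6.08 CPM. Whether its reads came from the cancer cells or from mouse cells was not tested either. The cytochrome P450 gene CYP1B1 fell by 5.66 ± 1.46 (edgeR adjusted p = 0.0108), from 184 to 34.5 CPM (71.5% of the latter in SUM149PT), and CYP1A1 fell by 4.07 ± 1.001, from a mean of 11.9 CPM, 89.97% of it in SUM52PE (median 1.397), to 0.274 CPM. SUSD3 fell by 5.11 ± 0.75, the transporter gene ABCG2 fell by 3.996 ± 1.023, and the elongation factor gene EEF1A2 by 3.94 ± 0.78, from 415 to 97.6 CPM (57.2% of the latter in MCF-7) in 10 of 10 lines. WISP2 fell by 3.88 ± 0.86, HES7 by 3.61 ± 0.76, GNG11 by 3.58 ± 0.89 and SEMA6B by 3.58 ± 0.77.

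Among the 22 other tested lists in the MIND comparison, camera adjusted p-values ran from 0.0566 for p53 targets to 0.965 for extracellular proteases. Glucocorticoid response genes (0.0997), oestrogen receptor targets (0.149) and the unfolded protein response (0.149) came next, followed by hypoxia and glycolysis, fibroblast markers, and smooth muscle and pericyte markers (each 0.199). Milk proteins had 0.227, TGF-beta and BMP pathway components 0.342, luminal identity and TGF-beta and SMAD targets each 0.442, and ribosomal proteins and the mitochondrial genome each 0.450. Epithelial-mesenchymal transition, cholesterol synthesis and replication-dependent histones had camera adjusted p-values of 0.569. Antigen presentation had 0.809, epithelial junction and identity, endothelial markers and adipocyte markers each 0.855, and leukocyte markers 0.955. In the TGF-beta and SMAD target list, 3 members rose and 4 fell, with 21 measured. Among them, ID1 fell by 2.71 ± 0.56 and ID3 by 2.12 ± 0.45, and PMEPA1 rose by 1.89 ± 0.46 (3 genes chosen after their values were seen). Genes lower in MIND tumours had a median GC content of 59.1%, higher ones 43.3%, and all tested genes 48.4%. The MIND to culture ratio correlated with GC content at a median of -0.199, with a negative value in 9 of 10 lines. The exception was SK-BR-5 (0.0401), the 1 line of the 10 whose MIND library stood in the other MIND table. Without the line as a block, 428 genes were called (205 higher, 223 lower) and the basal identity list had a camera adjusted p of 0.139. A fit of these 2 states alone gave 1696 calls, leaving out SUM149PT gave 1966, and leaving out SUM159PT gave a camera adjusted p of 0.0638 for the basal identity list.

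FP tumours were compared with cultures of the same 10 lines to ask which genes differed on growth in the fat pad. The edgeR test called 1392 of 16003 genes, 600 higher and 792 lower in FP tumours, with 420 higher and 172 lower at a 2-fold difference or more. The share of higher calls was 43.1%, against 60.02% with upper-quartile scaling. KRT14 rose by 7.73 ± 1.04 (edgeR adjusted p = 0.000525), from 2.60 to 249 CPM (55.9% of the latter in SUM159PT), and KRT17 by 4.68 ± 1.17, from 123 to 540 CPM, both in 10 of 10 lines. KRT75 rose by 4.62 ± 0.99. KRT6B rose by 3.24 ± 0.97 and SFN by 1.34 ± 0.37, each in 9 of 10 lines. In the basal identity list 6 of 14 members rose and 0 fell, and 7 rose when adjusted over the list alone (camera adjusted p = 0.00024; adjusted p = 0.510 with an estimated correlation). The list mean reached 6.68 in T-47D and was below 0 only in the library labelled SK-BR-7 (-0.55). The T-47D FP tumour also had the largest list means over lines for fibroblast markers (5.02), smooth muscle and pericyte markers (3.23) and leukocyte markers (3.21). Of 24 interferon response genes, 12 rose and 0 fell, and 18 rose when adjusted over the list alone (camera adjusted p = 9.01e-11; adjusted p = 0.425 with an estimated correlation). XAF1 rose by 4.46 ± 0.75, from 2.72 to 42.1 CPM, and OAS2 by 3.90 ± 0.72, from 8.57 to 84.7 CPM. IFI27 rose by 4.26 ± 0.91 (edgeR adjusted p = 0.00986) in 10 of 10 lines, from 6.74 to 206 CPM, and ISG15 by 2.20 ± 0.49, from 12.03 to 60.64 CPM.

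In the cell cycle list, 7 of 25 members fell in FP tumours and 0 rose, and 17 fell when adjusted over the list alone (camera adjusted p = 3.80e-08; adjusted p = 0.598 with an estimated correlation). TOP2A fell by 1.11 ± 0.21 (edgeR adjusted p = 0.00554), from 456 to 214 CPM. AURKA fell by 1.03 ± 0.22 in 10 of 10 lines, BUB1 by 1.16 ± 0.26 and CCNA2 by 1.10 ± 0.26. Of 16 amino acid starvation response genes, 3 fell and 0 rose, and 7 fell when adjusted over the list alone (camera adjusted p = 0.00024; adjusted p = 0.425 with an estimated correlation). MTHFD2 fell by 1.11 ± 0.16 in 10 of 10 lines, CHAC1 by 1.95 ± 0.49 and SHMT2 by 0.51 ± 0.15, and SLC3A2 had a log2 difference of -0.81 ± 0.25 (edgeR adjusted p = 0.0503). Immediate early genes included 4 that fell and 0 that rose of 16, and 6 that fell when adjusted over the list alone (camera adjusted p = 0.0419; adjusted p = 0.598 with an estimated correlation). FOS fell by 2.61 ± 0.58 (edgeR adjusted p = 0.0117), from 272 to 47.5 CPM, IER3 fell by 1.498 ± 0.366, EGR1 fell by 2.36 ± 0.62 and FOSB by 2.51 ± 0.67. In the hypoxia and glycolysis list, 3 of 23 members rose and 0 fell, also over the list alone (camera adjusted p = 0.00329; adjusted p = 0.598 with an estimated correlation). ANKRD37, a target of hypoxia-inducible factor, rose by 1.77 ± 0.38 in 10 of 10 lines, from 3.89 to 13.9 CPM. NDRG1 rose by 2.46 ± 0.59 in 8 of 10 lines, from 138 to 883 CPM, and KDM3A by 0.72 ± 0.20. ALDOA, with 0.60 ± 0.22 at a mean of 28.7 CPM in FP tumours, did not pass (edgeR adjusted p = 0.0896).

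Markers of connective tissue and of smooth muscle formed part of the FP comparison. Whether their reads came from the cancer cells or from mouse cells in the tumours was not tested. COL1A2 rose by 5.47 ± 1.26 (edgeR adjusted p = 0.0134) in 10 of 10 lines, from 0.174 to 458 CPM, and measured 4361 CPM in SUM159PT. It was the 1 fibroblast marker of 13 that rose, also over the list alone, and 0 fell (camera adjusted p = 0.0419; adjusted p = 0.598 with an estimated correlation). BGN, COL3A1 and COL1A1 had log2 differences of 2.70 ± 1.47, 2.27 ± 1.40 and 0.59 ± 0.39 and did not pass. The highest fibroblast marker by mean in FP tumours was COL1A1, with a mean of 621 CPM against 159 CPM in culture, a median of 38.0 CPM against 39.4 CPM, and a maximum of 5650 CPM in SUM159PT. Of 7 measured gene IDs of smooth muscle and pericyte markers, 1 of them annotated as antisense under the symbol RGS5, 0 passed among all tested genes and 2 rose when adjusted over the list alone (camera adjusted p = 0.0419; adjusted p = 0.510 with an estimated correlation). ACTG2, CSPG4 and TAGLN had log2 differences of 2.59 ± 0.88, 1.46 ± 0.54 and 1.38 ± 0.64, and the antisense ID 0.54 ± 0.25. NOTCH3 was the highest marker of that list at a mean of 186 CPM, against 110 CPM in culture. The elastin gene ELN rose by 4.97 ± 1.39, NXPH1 by 5.47 ± 1.01, CXCL17 by 5.20 ± 1.06, TNFRSF19 by 4.85 ± 0.85, AATBC by 4.57 ± 0.91, and the pseudogene AP002982.1, the source of whose reads was not tested, by 8.28 ± 0.61. Of 24 ribosomal protein genes, 0 passed, also over the list alone (camera adjusted p = 0.0419, higher; adjusted p = 0.822 with an estimated correlation), and RPS9, RPL13, RPS18 and RPL10A had log2 differences of 0.49 ± 0.17, 0.67 ± 0.27, 0.53 ± 0.22 and 0.34 ± 0.14.

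In FP tumours CYP1B1 fell by 6.30 ± 1.41 (edgeR adjusted p = 0.0117) and CYP1A1 fell by 4.11 ± 0.98. SUSD3 fell by 3.60 ± 0.70, LHX4 by 2.93 ± 0.57, TMEM56 by 2.56 ± 0.36 in 10 of 10 lines, HES7 by 2.54 ± 0.71, RN7SL3 by 2.39 ± 0.64 and ACSL1 by 2.37 ± 0.52. The efflux transporter gene ABCC2 fell by 2.84 ± 0.62, from 82.0 CPM (62.1% of it in the SK-BR-7 culture) to 3.77 CPM. Among the 18 other lists in the FP comparison, camera adjusted p-values ran from 0.0839 (antigen presentation, unfolded protein response, glucocorticoid response) to 0.809 (epithelial-mesenchymal transition). Without the line as a block, 17 genes were called (12 higher, 5 lower) and the fibroblast marker list had a camera adjusted p of 0.121. Leaving out MCF-7 gave 570 calls, a filter on mean CPM gave 881, no filter 816, DESeq2 2591, and a fit of these 2 states alone 339, and with the GC correction camera adjusted p-values were 0.0528 for fibroblast markers, 0.0528 for ribosomal proteins and 0.0506 for smooth muscle and pericyte markers. Hypoxia and glycolysis had a camera adjusted p of 0.0518 without MCF10DCIS.com, and immediate early genes had 0.155 without MCF-7.

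FP and MIND tumours labelled with the same 10 lines were compared to ask which genes differed between the 2 sites of growth. Only the MIND libraries carried the tag for filtered reads, so that a difference in filtering could not be separated from the site. The edgeR test called 1402 genes, 963 higher and 439 lower in FP tumours (68.7% higher, against 64.6% with upper-quartile scaling), with 447 higher and 59 lower at a 2-fold difference or more. Genes higher in FP tumours had a median GC content of 62.4%, and lower ones 38.7%. The FP to MIND ratio correlated with GC content in 10 of 10 lines at 0.00605 (SK-BR-5) to 0.608, with a median of 0.413. With offsets corrected for GC content, 62 genes were called, 54 higher and 8 lower in FP tumours. Genes called both with and without the correction included 5 of the 10 named increases. C4orf48 rose by 4.04 ± 0.74 (edgeR adjusted p = 0.00207), from 0.416 to 5.13 CPM, and the mitochondrial ribosome gene MRPL12 by 2.74 ± 0.36 (0.000344), from 2.98 to 20.4 CPM, both in 10 of 10 lines. MZT2B rose by 2.48 ± 0.40 in 10 of 10 lines, from 12.4 to 62.2 CPM, PRR7 by 3.11 ± 0.49 and CCDC85B by 2.81 ± 0.44. Corrected log2 differences of these 5 were 2.55 ± 0.56 for C4orf48, 1.88 ± 0.26 for MRPL12, 1.30 ± 0.24 for MZT2B, 1.58 ± 0.32 for PRR7 and 1.64 ± 0.30 for CCDC85B. Without the correction only, EVA1B rose by 2.86 ± 0.66, TMEM121 by 2.68 ± 0.58, SNHG25 by 2.63 ± 0.69, PHLDA2 by 2.54 ± 0.52 and KREMEN2 by 2.43 ± 0.53. With it their log2 differences were 1.94 ± 0.62, 1.25 ± 0.49, 1.89 ± 0.59, 1.77 ± 0.41 (edgeR adjusted p = 0.0604) and 1.15 ± 0.39, in the same order. Over all 1402 calls the correction left a median of 0.348 of the log2 difference, and 148 turned direction. Of the 10 named decreases, BEST1 was called with the correction too, which fell by 1.94 ± 0.48 in 10 of 10 lines, from 5.87 to 1.43 CPM. The other 9 included SELENOP, which fell by 1.88 ± 0.58, from 384 CPM (52.6% of it in T-47D) to 94.7 CPM, TMEM56, which fell by 1.69 ± 0.36, and ZNF577, which fell by 1.63 ± 0.37. Corrected log2 differences were -1.35 ± 0.57 for SELENOP, -1.19 ± 0.31 for TMEM56 and -1.36 ± 0.38 for ZNF577. FSIP2 had -2.92 ± 0.88 before and -2.41 ± 0.84 after correction, AC010329.1 -2.31 ± 0.68 and -2.13 ± 0.69, and C12orf60 -1.52 ± 0.44 and -1.38 ± 0.44.

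Immediate early genes were higher in FP than in MIND tumours, with 3 of 16 members that rose and 0 that fell, also over the list alone (camera adjusted p = 0.0110; adjusted p = 0.936 with an estimated correlation). JUNB rose by 2.10 ± 0.35 (edgeR adjusted p = 0.0012), from 24.1 to 94.6 CPM, IER2 by 0.995 ± 0.223 and ZFP36 by 0.64 ± 0.20, each in 10 of 10 lines. FOS had a log2 difference of 1.20 ± 0.53 (edgeR adjusted p = 0.163). With the GC correction the list had a camera adjusted p of 0.0312, JUNB had a log2 difference of 1.22 ± 0.27 (edgeR adjusted p = 0.0529), and IER2 and ZFP36 were not called. Of 24 ribosomal protein genes, 4 rose and 0 fell, also over the list alone (camera adjusted p = 0.00552; adjusted p = 0.936 with an estimated correlation). They were RPS2 (0.82 ± 0.20), RPL18 (0.76 ± 0.20), RPS9 (0.65 ± 0.18) and RPL8 (0.74 ± 0.22), and none of these 4 was called with the GC correction, with which the list had a camera adjusted p of 4.76e-07. Without the libraries labelled SK-BR-7, the ribosomal protein list had a camera adjusted p of 0.170. The other 25 tested lists had camera adjusted p-values from 0.288 (TGF-beta and SMAD targets, p53 targets) to 0.949 (luminal identity), with 0.813 for interferon response and 0.631 for basal identity and for cell cycle. Without the line as a block, 135 genes were called (131 higher, 4 lower). Leaving out Evsa-T gave 728 calls, no filter gave 687, and DESeq2 gave 2262.

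**Figure D3:**
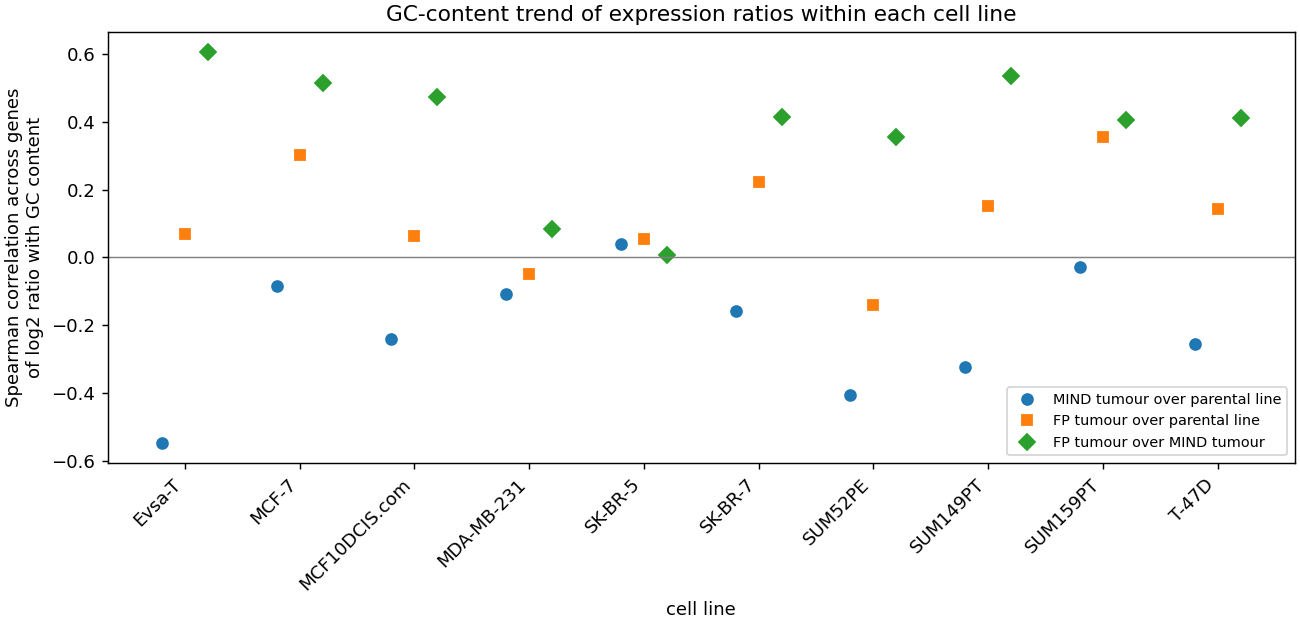
Spearman correlation, across genes, of GC content with the log2 ratio between states, per line. Each point is 1 line.

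The overlap of the MIND and FP differences from culture was examined because both used the same 10 cultures. Of the genes called, 681 differed in the same direction in both comparisons (400 higher, 281 lower) and 1 in opposite directions, against 53.9 higher and 75.8 lower for independent lists. At a 2-fold difference or more, 379 were shared (294 higher, 85 lower). Log2 differences correlated at 0.703 over all tested genes, with a covariance of 0.335. In simulations with shared cultures and no true difference, the mean correlation was 0.489 (SD 0.0104), the covariance 0.0657, and the mean number of shared genes 0. With MIND differences taken from 5 lines and FP differences from the other 5, correlations were 0.387 and 0.382 and covariances 0.247 and 0.227. These fits of 5 lines called 0 and 6 genes for MIND and 0 and 0 for FP, so that no shared calls were possible.

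SMAD4, the transcription factor gene named in the series title, was examined in every library. SMAD4 (ENSG00000141646, chromosome 18, 51028394 to 51085045) averaged 49.5 CPM in cultures, 55.5 CPM in MIND tumours and 45.2 CPM in FP tumours of the 10 lines. It did not pass in any of the 3 comparisons, with log2 differences of 0.08 ± 0.21 for MIND against culture (edgeR adjusted p = 0.828, higher in 7 of 10 lines), -0.14 ± 0.21 for FP against culture (0.705, higher in 5) and -0.22 ± 0.21 for FP against MIND (0.542, higher in 4). Culture levels ran from 23.5 CPM in MCF-7 to 76.4 CPM in SK-BR-7. Among the 19 MIND tumours, levels ran from 0.648 CPM in MDA-MB-468 to 105 CPM in BT-474, with a median of 41.1 CPM. MDA-MB-468 had 10 SMAD4 counts, or 0.658 CPM before scaling (exact Poisson 95% interval 0.315 to 1.21). FP levels ran from 13.998 CPM in the library labelled SK-BR-7 to 76.3 CPM in MDA-MB-231.

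Because the series title names SMAD4 and its design asks about invasiveness, the SMAD4 level was set against 6 list scores across the 19 MIND tumours, with permutation p-values. None of the 6 relations passed the correction. The largest was with epithelial junction and identity (r = -0.343, permutation p = 0.141, adjusted p = 0.847; rho = -0.461, permutation p = 0.0483, adjusted p = 0.290). Correlations were 0.0708 for epithelial-mesenchymal transition (permutation adjusted p = 0.940), 0.00451 for TGF-beta and SMAD targets (0.985), -0.226 for basal identity (0.878), -0.144 for luminal identity (0.878) and -0.146 for cell cycle (0.878). The epithelial-mesenchymal transition score rested on 3 genes and the basal score on 5. Within the 9 MIND tumours of 1 deposited table, luminal identity correlated with SMAD4 at -0.807 (exact permutation p = 0.00906, adjusted p = 0.0544; rho = -0.883, exact permutation p = 0.00308, adjusted p = 0.0185). Within the 10 tumours of the other table this correlation was 0.407. The epithelial correlation was -0.493 (rho = -0.683) within the first table and -0.199 (rho = 0.139) within the second, and -0.493 (permutation adjusted p = 0.261) without MDA-MB-468 and SUM149PT, the 2 tumours farthest from the median SMAD4.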

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

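Tests of the GC trend of FP against MIND tumours, of basal keratins and of the sources of the tumours labelled SK-BR-7, fits with the GC correction or without the SK-BR-7 libraries, and the tests of the last part were chosen after the result was seen. The check for a single sample far from its group was run on 153 groups of values and singled out 11, where chance alone, at 1 in 20, gives 7.65. In cultures, SUM52PE stood apart from the other lines with 25.3% mitochondrial counts, against 13.03% in the next. Among own-line correlations, the libraries labelled SK-BR-7 stood apart in both tumour groups, at 0.742 in MIND tumours and 0.731 in FP tumours. The COL1A2 difference from culture was 14.40 in the SUM159PT MIND tumour, against 7.05 in the next line. CYP1A1 differed by -9.78 in the SUM52PE MIND tumour, against -4.47. In the T-47D FP tumour, KRT6B differed by 9.25, against 4.25, and ACTG2 by 8.18, against 2.60. SMAD4 differed by -2.20 in the FP tumour labelled SK-BR-7, against -0.40. Between FP and MIND tumours, SNHG25 differed by -2.86 in SK-BR-5, against 1.36, ZNF577 by 1.59 in MCF-7, against -0.86, and FOS by 3.94 in T-47D, against 1.63.

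A difference between the effects of the 2 sites, by the camera test of FP against MIND tumours, was recorded for immediate early genes (median 0.65 on the log2 scale over members) and ribosomal proteins (0.23), each with an adjusted p of 0.936 at an estimated correlation. Without the libraries labelled SK-BR-7 the ribosomal protein list had a camera adjusted p of 0.170. In the MIND tumours of lines without a cultured library, which the comparisons did not use, 6 of 9 had an interferon response score above that of every culture. These were MDA-MB-453 (mean log2 CPM 9.23), SUM225CWN (5.58), HCC1937 (4.50), MDA-MB-175-VII (4.46), SK-BR-3 (4.21) and MDA-MB-468 (3.88), against 3.72 in the highest culture, MDA-MB-231. BT-20 (2.98), BT-474 (1.09) and CAMA-1 (1.05) were not above it, with a culture median of 2.26. For basal identity 1 of 9, HCC1937 (9.18), was above the highest culture, MCF10DCIS.com (8.66). Without a culture of the same line, a rise in these tumours could not be told from the line's own level.

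Genes that differed between the states were weighed against sequence composition. For FP against MIND tumours a GC trend fits, with a median correlation of 0.413 over 10 lines, and 3.99% of calls and a median of 0.348 of the log2 difference kept after correction, and the biological explanation, the site of growth, shared its tables and was not separable. The tag for filtered reads, on the MIND libraries only, was not separable from the site either, and its effect was not tested. For genes lower in MIND tumours than in culture, the GC trend (-0.199) leaves the explanation open, since 57.1% of the falls were kept after correction. Lower read totals were left open, since the GC correlation of the FP libraries (0.107) did not bear on them and FP libraries with similar totals had 792 lower calls. Degraded RNA was left open by the correlation with transcript length (0.0384).

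Basal keratins higher in tumours than in culture were weighed against mouse cells in the counts. Over the 8 tumours, of 4 lines, with a rise of KRT5 plus KRT14 above 100 CPM, contractile genes of myoepithelial cells rose by a median of 0.0388 of the keratin rise. This ratio cannot decide on mouse myoepithelial cells. Whether mouse reads of both gene sets were counted equally was not tested, and each rise was net of the line's own level in culture. In those above 1000 CPM, the ratio of fibroblast genes to keratins ran from -0.00979 in the SUM149PT MIND tumour to 12.7 in the SUM159PT MIND tumour, which left mouse fibroblasts open. The contractile ratio of the T-47D FP tumour (0.558) and the fibroblast ratio of the SUM159PT tumours (at least 3.80) were singled out because they were high, and left mouse cells in these tumours open. Cells of SUM225CWN could not give the whole rise in T-47D, whose tumours had 736 and 1014 CPM of KRT5, against 491 CPM in the SUM225CWN tumour. ERBB2 in the T-47D tumours reached at most 1.88% of the level needed. That test added little, since the level needed (31003 and 42711 CPM) exceeded the 20698 CPM of the SUM225CWN tumour itself. Lines with a higher KRT5 level, such as HCC1937, were not tested as a source. The biological explanation, growth in the mouse, was carried by the same libraries, and was not tested apart from these.

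The tumours labelled SK-BR-7 were weighed against a change of the line on growth, a swap and another line. A swap of FP libraries would leave another FP tumour close to the SK-BR-7 culture, but 0 of the other 9 FP tumours were closer to the SK-BR-7 culture than to their own. The FP tumour correlated at 0.992 with the MCF-7 FP tumour, above all 9 own-line pairs of MIND and FP tumours (0.912 to 0.982). It differed from it by a chi-square per gene of 7.79, against 66.1 for the MCF10DCIS.com pair. Both contrasts are unlike, since own-line pairs cross deposited tables. The 2 FP libraries also had lower totals (6663586 and 8299837) than the MCF10DCIS.com pair (15821150 and 15315836), and this chi-square grows with counts. Across tables, the FP tumour correlated at 0.917 with the MCF-7 culture, within the own-line range of the other 18 tumours (0.868 to 0.959). These values fit cells or RNA of another line in the FP tumour and speak against a change of the line on growth as its source. For the MIND tumour both were left open, since it reached 0.924 with the SUM225CWN tumour, within the range of own-line pairs, and its own-line correlation (0.742) was the observation to be explained.

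Swapping state labels within lines in 40 splits tested whether chance could give the counts of calls. For MIND against culture 1 of 40 splits, the real one, gave as many as 2969, and the highest other gave 480. For FP against culture 1 of 40 gave 1392, and the highest other 34. For FP against MIND 1 of 40 gave 1402, and the highest other 0. The real labels gave more calls than every other split tried. With 40 splits 1 of 40 was the smallest share possible, and swapping moves a true difference into the spread, so chance was not excluded. The splits also cannot separate state from table.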

How the results depend on the processing

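Depth and design limit these results, with 1 library per line and state, no replicate of a line, and state joined with table. In simulated counts 5.97% of genes changed 1.5-fold were recovered for MIND against culture, so that small differences were mostly missed. Of the 1863 alternative values of 118 named results, SMAD4 not among them, 1604 kept direction and side of the threshold, 249 lost the call, 9 gained it and 1 turned. The SMAD4 difference of FP against MIND, not called in either fit, turned from -0.223 to 0.0850 ± 0.178 with the GC correction (edgeR adjusted p = 0.957). Without the block, 79 of 118 named results lost the call, and with the GC correction 21 did. RLE and upper-quartile scaling moved no total of calls by over 1.5 times, nor did testing protein-coding genes alone, but with upper-quartile scaling the lower calls of FP against culture went from 792 to 495. Own-line matches stayed at 18 with Pearson correlation. For every move below that a smaller number of genes or lines does not account for, the cause was not tested.

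Without the line as a block, calls were 428 for MIND against culture, 17 for FP against culture and 135 for FP against MIND, keeping 14.2%, 1.22% and 9.63% of the main calls. Without it the camera adjusted p was 0.139 for basal identity in MIND tumours (range over all its alternatives 0.00126 to 0.659) and 0.121 for fibroblast markers in FP tumours (0.000995 to 0.598). It changed no other call of a list. A fit of 2 states alone gave 1696 and 339 calls against culture. Requiring a log2 difference of 1 gave 1470, 592 and 506 calls and an overlap of 379. With no filter, calls were 816 for FP against culture and 687 for FP against MIND, and at a mean of 5 CPM 881 for FP against culture. DESeq2 gave 2591 and 2262 calls for these comparisons. With MIND and FP differences from separate sets of 5 lines, the overlap was 0 and 0, which the small number of lines fixed, since FP differences gave 0 calls in both splits.

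With an estimated correlation, 0, 0 and 0 lists were called in the 3 comparisons. For MIND against culture, adjusted p-values were then 0.659 for cell cycle and basal identity, 0.485 for interferon response, and 0.256 for amino acid starvation and immediate early genes. For FP against culture they were 0.598 for hypoxia, cell cycle, immediate early genes and fibroblast markers, 0.425 for interferon response and amino acid starvation, 0.510 for basal identity and smooth muscle markers, and 0.822 for ribosomal proteins. For FP against MIND they were 0.936 for both called lists. With fry, adjusted p-values were 0.0699 for hypoxia and 0.351 for ribosomal proteins in FP against culture, and 0.177 for immediate early genes and 0.421 for ribosomal proteins in FP against MIND, where it called 0 lists.

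Alternatives chosen after the data were seen were the GC correction, fits without the SK-BR-7 libraries, leaving out lines in list tests, and the SMAD4 relations without the SK-BR-7 or the MDA-MB-468 tumour or with other list genes. With the GC correction, FP against MIND gave 62 calls, ribosomal proteins and fibroblast markers in FP against culture had camera adjusted p-values of 0.0528 each and smooth muscle markers 0.0506 (range over its alternatives 0.00233 with fry to 0.510 with an estimated correlation), and the RPL8 difference turned to -0.0579. Without the SK-BR-7 libraries, calls were 3018 for MIND against culture, 1170 for FP against culture and 1173 for FP against MIND. These fits kept 83.7%, 69.5% and 71.8% of the main calls. For MIND against culture 8 lists were then called, including every list called in the main test. Ribosomal proteins in FP against MIND had a camera adjusted p of 0.170 (range 4.76e-07 to 0.936), and SMAD4 in FP against culture turned to 0.0777 (edgeR adjusted p = 0.794).

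Leaving out each line in turn gave 1966 to 3018 calls for MIND against culture, 570 to 1423 for FP against culture and 728 to 1684 for FP against MIND, and 5 to 8, 6 to 12 and 2 to 2 lists. For MIND against culture, camera adjusted p-values ran from 2.37e-10 to 8.52e-06 for cell cycle, 4.58e-11 to 3.63e-07 for interferon response, 0.0025 to 0.0638 for basal identity, 1.8e-05 to 0.00227 for amino acid starvation and 7.03e-06 to 0.000712 for immediate early genes. For FP against culture, they ran from 2.68e-05 to 0.0518 for hypoxia, 1.18e-10 to 8.87e-06 for cell cycle, 2.63e-13 to 1.17e-08 for interferon response, 4.72e-06 to 0.00702 for basal identity, 4.53e-05 to 0.00413 for amino acid starvation, 0.00344 to 0.155 for immediate early genes, 0.0184 to 0.122 for ribosomal proteins, 0.000995 to 0.223 for fibroblast markers and 0.0318 to 0.112 for smooth muscle markers. For FP against MIND, they ran from 0.00061 to 0.170 for ribosomal proteins and 0.00456 to 0.0402 for immediate early genes.

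Pearson correlations with SMAD4, none of which passed, turned direction as follows. Within the table of 9 tumours, basal identity gave 0.421 and cell cycle 0.0393. Within the table of 10, epithelial-mesenchymal transition gave -0.385, TGF-beta and SMAD targets -0.449 and luminal identity 0.407. With a prior count of 0.5, TGF-beta and SMAD targets gave -0.00161. Without the 2 tumours farthest from the median, cell cycle gave 0.222, and without MDA-MB-468 it gave 0.285 and basal identity 0.0321. Spearman correlations turned to 0.139 for epithelial junction and identity, -0.418 for epithelial-mesenchymal transition, -0.6 for TGF-beta and SMAD targets and 0.370 for luminal identity within the table of 10. For basal identity they turned to 0.533 within the table of 9, 0.0123 without the 2 farthest tumours and 0.0939 without MDA-MB-468.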

Other observations

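Receptor and lineage genes differed widely between the 39 libraries. ESR1 was highest in the MCF-7 MIND tumour, at 773 CPM, against 282 CPM in MCF-7 culture and 320 CPM in the FP tumour, and reached 593 CPM in CAMA-1, 331 CPM in MDA-MB-175-VII, 157 CPM in BT-474 and 87.6 CPM in SK-BR-3 MIND tumours. In T-47D it measured 292 CPM in culture, 131 CPM in the MIND tumour and 8.26 CPM in the FP tumour. PGR, a target of the oestrogen receptor, measured 1165, 2.77 and 0.163 CPM in the same T-47D libraries and 146, 8.82 and 1.41 CPM in those of MCF-7. ERBB2 was highest in the MIND tumour labelled SK-BR-7 (21042 CPM) and in SUM225CWN (20698 CPM), followed by BT-474 (10575 CPM), SK-BR-3 (3456 CPM) and MDA-MB-453 (1633 CPM). CDH1, which encodes E-cadherin, measured 0.452 CPM in the MIND tumour of MDA-MB-231 and 11.2 CPM in that of SUM159PT, against 1836 CPM in BT-474. VIM, which encodes vimentin, measured 8018 CPM in MDA-MB-231, 2542 CPM in SUM159PT and 2199 CPM in MCF10DCIS.com MIND tumours, and 0.485 CPM in MDA-MB-453. VIM in the libraries labelled SK-BR-7 measured 566 CPM in culture, 4.96 CPM in the MIND tumour and 1.9996 CPM in the FP tumour. These are single libraries, and no test between lines was run. The labels of the 9 lines without a culture, SK-BR-3 among them, could not be checked against their own line.

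Basal genes varied between lines and states. KRT5 measured 0.0466 CPM in T-47D in culture, 736 CPM in its MIND tumour and 1014 CPM in its FP tumour, and TP63, a regulator of basal epithelium, 0.977, 109 and 132 CPM. In SUM159PT KRT5 measured 0.183, 3184 and 1685 CPM, and in SUM149PT KRT14 measured 3.74, 2679 and 215 CPM. HCC1937 had the highest MIND level of KRT5 (4766 CPM), with 1248 CPM of S100A7 and 2865 CPM of PI3, which are genes of stratified epithelium. The MDA-MB-453 MIND tumour had the highest levels of ISG15 (1513 CPM) and IFI27 (3590 CPM) of all 39 libraries. In other-cell lists, the highest member by mean in MIND and FP tumours was COL3A1 (1736 CPM, median 2.83) and COL1A1 for fibroblasts, ESAM (10.5 CPM) and EGFL7 (19.8 CPM) for endothelium, LAPTM5 (15.8 and 28.5 CPM) for leukocytes, CD36 (23.8 CPM) and PLIN4 (8.92 CPM) for adipocytes, MB (21.4 and 31.2 CPM) for skeletal muscle, NOTCH3 (108 and 186 CPM) for smooth muscle and pericytes, HBA1 (0.0499 and 0.407 CPM) for erythroid cells, and LIPH (55.1 CPM) and XDH (38.4 CPM) for milk. In culture these genes averaged 52.8, 159, 20.6, 27.8, 15.3, 2.90, 11.01, 18.1, 110, 0.120, 38.8 and 52.5 CPM, in the same order. Tumour medians were far below these tumour means for ESAM (0.907 CPM), LAPTM5 (0.332 and 0.519 CPM), CD36 (2.14 CPM) and XDH (2.97 CPM). ESAM and LAPTM5 were highest in MDA-MB-231 tumours. The pseudogene AP002982.1, present in 18 tumours at 1.94 CPM or more and in the 9 cultures of the same lines at 0.0977 CPM or less, was the 1 gene of all those searched that had at least 1 CPM in each of these tumours and less than 0.5 CPM in each culture, with a culture mean below 0.1 CPM, without the libraries labelled SK-BR-7. Whether its reads came from the cancer cells or from mouse cells was not tested.

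A first hypothesis was that interferon genes rise more in tumours with more stromal transcripts. Over 9 lines, without the libraries labelled SK-BR-7, the mean interferon difference correlated with the mean fibroblast marker difference at r = 0.661 (exact permutation p = 0.0526, adjusted p = 0.105; rho = 0.55, exact permutation p = 0.133). Without the 2 farthest lines r was 0.0556, and the relation was left open. A second hypothesis was that lines with the largest cell cycle decrease have the largest interferon increase. The correlation was -0.454 (exact permutation p = 0.219, adjusted p = 0.219; rho = -0.533, exact permutation p = 0.148), and -0.372 without the 2 farthest lines, which left it open too.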
